A study of Mus musculus with 8 samples.

How the data were processed

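The samples are 8 ATAC-seq libraries of bone marrow-derived macrophages from 2 wild-type C57Bl/6 mice, each mouse giving 1 library for unstimulated cells, fenoterol, LPS, and fenoterol then LPS. Per the labels' protocols, crude nuclei were treated with Tn5 transposase, the DNA was amplified with barcoded primers, and fragments were size selected on a gel. Per the submitters' processing notes, the tools were cutadapt, Bowtie2, MACS2 and HOMER, with no versions named, and the genome build was mm9. Removal of duplicate or mitochondrial reads, a shift of reads for the Tn5 cut site and the use of pooled or separate libraries for peak calling are not given in the sources used here. The peak set was shared by all libraries.

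The deposited table gives 1 RPKM value per peak and library, made by the authors, with a name, chromosome, start and end for each of 74207 peaks on 21 chromosomes. Multiplied by peak length (end minus start, in kb), all values (100%) came within 0.01 read of whole multiples of 1 step per library, and the products of a library summed to nearly the same total in all 8. The RPKM is therefore relative to reads in peaks, and reads per peak could be recovered. The excess of each sum over that total equals what peaks without reads add when set to 1 read; by this reckoning 1598 peaks were so set in the unstimulated library of mouse 1 and 20 to 202 in the others. A level of 1 read is therefore not evidence of a read. Coordinates are given as the file gives them; the minimum width, counted inclusively, is 200 bp, at 3404 peaks.

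Reads in peaks were 1426873 and 4040292 for unstimulated cells of mouse 1 and mouse 2, 3164446 and 3753955 for fenoterol, 3521741 and 3637389 for LPS, and 3918319 and 3535300 for fenoterol + LPS. The median peak held 9 reads in the shallowest library and 21 to 28 in the others, so single values of low peaks in the unstimulated library of mouse 1 are the least precise. No pair of libraries was counted as 1 sample: the chi-square over degrees of freedom of recovered reads, over peaks with at least 20 reads, was 0.89 to 1.21 for the 4 pairs of a group, but each group has 1 pair only and pairs of different groups came as low as 0.97.

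Values were scaled by median-ratio size factors (0.9401 to 1.037), a pseudocount of 4 was added and log2 taken. The lowest 10% of peaks by mean, under 9.71 RPKM, were left out (7421 peaks), and 66786 were tested with limma 3.58.1 in R 4.3.3 (limma-trend, moderated statistics with a mean trend, Benjamini-Hochberg adjustment, threshold 0.05). The fit had 4 group means over all 8 libraries, so the groups share 1 estimate of spread with 4 residual degrees of freedom. Contrasts were LPS against unstimulated, fenoterol against unstimulated, fenoterol + LPS against LPS, fenoterol + LPS against fenoterol, and their interaction; an additive fit gave the average effects of LPS and fenoterol. Fold changes are on the log2(value + 4) scale and understate the ratio of the levels, most at low peaks. RPKM means and SDs in the text are of scaled values. The words rose and fell are used of peaks past the threshold.

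Because reads could be recovered, limma voom on reads was added after seeing the data, alone, with the mouse as a block, and with cyclic loess. The deposited unit is RPKM, so limma-trend stayed the main test. Cyclic loess of the log2 values and a fit on the 4 libraries of the groups compared were also added. Planned before the data were examined were the values as deposited, quantile normalization, pseudocounts of 0.8 and 20, no filter, the lowest 25% left out, no mean trend, the mouse as a block, a 1.5-fold in place of the 2-fold threshold, and leaving out each library in turn.

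Libraries with the same mouse number come from the same animal per the labels, so the numbers pair the samples. Differences between the mice correlated weakly across groups, at 0.0231 to 0.0727. The p-values rest on the spread between 2 animals per group, moderated towards a spread shared over peaks. That shared spread counted as 16.4 degrees of freedom in limma-trend and 135 in voom, against 4 residual ones. It therefore outweighs the spread between animals at a single peak, most of all in voom.

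Both tests were tried on simulated data at the real means and library sizes, with 66786 peaks tested. Among these, 66, 65 and 64 peaks were changed 1.5-, 2- and 3-fold for LPS against unstimulated, and 67, 61 and 63 for fenoterol + LPS against LPS. For LPS against unstimulated, limma-trend recovered 0% of 1.5-fold, 23.1% of 2-fold and 60.9% of 3-fold changes with 2 false calls, and voom 9.09%, 41.5% and 73.4% with 4. For fenoterol + LPS against LPS, limma-trend recovered 1.49%, 32.8% and 66.7% with 0 false calls, and voom 4.48%, 49.2% and 81.0% with 1. In 5 simulations without changes neither test called a peak in any of the 5 contrasts. Simulated reads were drawn independently, with a spread set by mean reads alone and no effect shared by the libraries of a group. The absence of calls therefore does not show that calls in the real data are free of such effects. Far fewer peaks were changed than LPS called, so the recovered shares do not carry over to the LPS comparison.

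Peaks were named by a rule fixed before the data were examined: among peaks past the threshold that moved the same way in both mice, the 12 with the highest rise and the 12 with the largest fall, and with fewer than 5 calls in a direction also the 5 of that direction with the smallest unadjusted p. The text gives the values of some of them and summarises the rest. Shifts at LPS-gained and LPS-lost peaks were measured in the mouse not used for the selection and set beside 10000 random sets matched on mean value in 20 bins. Other computing used Python 3.11.15 and matplotlib 3.10.9.

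The gene table at hand is on GRCm38, a different build: 748 peaks on 9 chromosomes lie beyond its last gene. Coordinates were not converted between builds, so no peak is given a gene, exon, intron or promoter annotation, and the planned tests of 16 gene lists, of peaks at Il1b, of promoter against distal peaks, of sequence motifs and of 1 peak per gene were not run and are not analysed here.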

Results

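Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in bone marrow-derived macrophages of wild-type C57Bl/6 mice. Cells of 2 mice were each kept unstimulated, given fenoterol, given LPS, or given fenoterol and then LPS, which makes 8 libraries in 4 groups with n = 2 mice per group. Fenoterol is an agonist of the β2 adrenergic receptor and was used at 1 µM for 15 min. LPS, a bacterial lipopolysaccharide that activates macrophages through Toll-like receptor 4, was used at 100 ng/mL for 1 h. Cells given fenoterol alone were treated for 15 min, per the labels, whereas cells given both had a further 1 h with LPS, so time since the agonist differed between the groups with fenoterol. The table held 74207 peaks on build mm9 with a median width of 405 bp, and 66786 of them were tested. Reads in peaks came to 1426873 in the unstimulated library of mouse 1 and to between 3164446 and 4040292 in the other 7. The median peak held 9 reads in the first of these libraries, with an exact 95% Poisson interval of 4.12 to 17.1, and 28 reads in the unstimulated library of mouse 2, with an interval of 18.6 to 40.5. These intervals cover counting error only.

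Accessibility profiles separated first by LPS. The first principal component held 49.6% of the variance and placed the 4 libraries without LPS between -72.1 and -43.6 and the 4 with LPS between 44.6 and 70. The third component held 8.71% and parted the LPS libraries, at -35.4 and -38.5, from the fenoterol + LPS libraries, at 34.8 and 25.2. The fenoterol libraries lay at -10.1 and 13.4 on this axis and the unstimulated libraries at 6.28 and 4.38. The second component held 16.2% and set the unstimulated library of mouse 1, at 79, apart from the other 7, which lay between -33.3 and 5.67. Correlations of log2 accessibility were 0.863 to 0.905 between the 2 mice of a group, 0.853 to 0.911 between groups with the same LPS state, and 0.699 to 0.794 between libraries with and without LPS. Among the libraries with LPS, the 2 mice correlated at 0.905 within the LPS group and at 0.905 within the fenoterol + LPS group, above the 0.873 to 0.883 of the 4 pairs across these groups. Among those without LPS no such gap was seen: the fenoterol libraries correlated at 0.901 with each other and at 0.902 and 0.911 with the unstimulated library of mouse 2, and the shallow unstimulated library of mouse 1 at 0.853 to 0.863 with these 3.

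**Figure D1:**
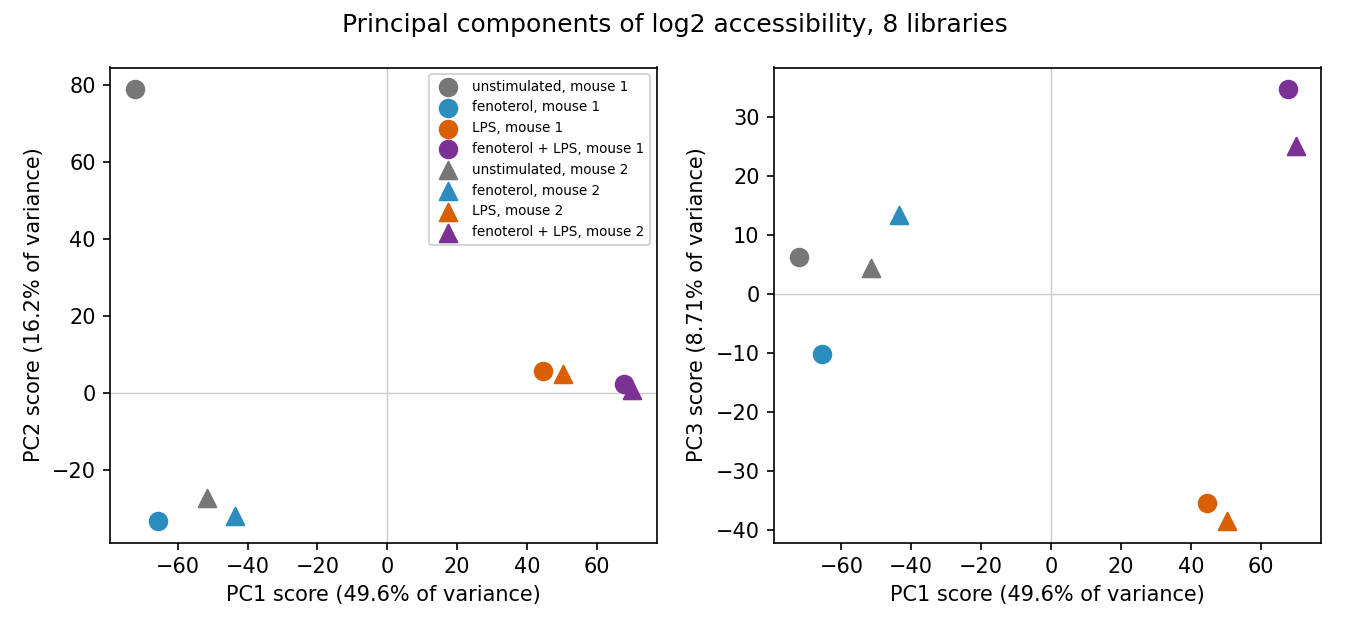
Scores of the 8 libraries on the principal components of log2 accessibility, with PC1 against PC2 on the left and PC1 against PC3 on the right; circles are mouse 1 and triangles mouse 2. LPS separated along PC1 (49.6% of variance), fenoterol + LPS from LPS along PC3 (8.71%), and the unstimulated library of mouse 1 stood at 79 on PC2.

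With LPS for 1 h, more regions gained accessibility than lost it. Values are relative to reads in peaks, so a shift common to all peaks would not be seen. Of 66786 peaks, 4363 rose and 2362 fell against unstimulated cells, together 10.1% of those tested. Median accessibility of the peaks that rose went from 10.8 RPKM in unstimulated cells to 28.4 RPKM with LPS, and that of the peaks that fell from 37.2 to 21.5 RPKM. Folds and log2 changes here are of the scaled value + 4 RPKM, so they are smaller than the ratio of the levels. The risen peaks changed by a median log2 of 1.09 and 2536 of them (58.1%) by at least 2-fold, whereas the fallen peaks changed by a median log2 of -0.70 and 339 (14.4%) by at least 2-fold. Expressed within each mouse, 1573 peaks were at least 2-fold higher in both mice, 126 at least 2-fold lower in both, and 24 went at least 2-fold in opposite ways.

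The 12 peaks with the highest rise changed 5.26- to 7.68-fold. On this scale the region with the highest rise lay on chromosome 14 at 103457007 to 103457218 and went from 8.15 ± 3.48 RPKM to 87.7 ± 10.3 RPKM (SD, n = 2; log2 change 2.94, SE 0.30, adjusted p = 4.32e-06). Its neighbour at 103456180 to 103456905 went from 14.0 ± 0.582 to 100 ± 9.88 RPKM, a 5.78-fold change. A region on chromosome 5 at 91334507 to 91334824 rose from 6.14 ± 2.03 to 60.0 ± 13.6 RPKM (6.30-fold, adjusted p = 3.31e-07). The change with the smallest adjusted p, 1.45e-07, was at 56588293 to 56589469 on chromosome 12, which rose from 7.58 ± 0.843 to 60.8 ± 1.86 RPKM (5.60-fold). At 4 of the 12 an unstimulated value lay at the floor of 1 read. The region on chromosome 16 at 15984293 to 15984766 is 1 of them, with 1.58 RPKM at the floor in mouse 1 and 2.54 RPKM in mouse 2, against 30.5 and 36.1 RPKM with LPS. Its log2 change was above that of the chromosome 14 region at 103457007 by voom (3.75 against 3.46). The same held with the pseudocount 5 times lower (3.59 against 3.36). The 12 peaks with the largest fall changed 2.74- to 3.42-fold. Of these calls, 6 were lost without the unstimulated library of mouse 1, 3 without the LPS library of mouse 1 and 4 without that of mouse 2, together 7 peaks; the calls of the 12 risen peaks were kept under all 21 alternatives. The broad peak at 24908220 to 24909667 on chromosome 13 fell from 57.7 ± 0.103 to 14.6 ± 2.88 RPKM (log2 change -1.74, SE 0.17, adjusted p = 4.06e-06). On chromosome 2, the region at 26331622 to 26331908 fell from 19.7 ± 1.69 to 2.90 ± 0.0891 RPKM (log2 change -1.78, adjusted p = 0.00113). The chromosome 13 call was kept under all 21. With the lowest 25% of peaks left out, only 4 of the 12 fallen peaks were tested, and the chromosome 2 peak was not among them. The chromosome 2 call was kept under every other alternative. Each of these 24 peaks moved the same way in both mice, which the rule for naming them required. The share of tested peaks that rose ran from 4.38% on chromosome X to 8.28% on chromosome 16, leaving out chromosome Y, where 0 of 32 rose. The total of 6725 peaks became 12508 without the unstimulated library of mouse 2, 2814 without the LPS library of mouse 1 and 2077 without that of mouse 2. Voom on recovered reads gave 7967 peaks, and 2257 without the unstimulated library of mouse 2, so this omission moved the counts of the 2 tests in opposite ways.

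With fenoterol present, most peaks that LPS alone moved went the same way in both mice. The group means of this comparison, of fenoterol + LPS with fenoterol, share no library with those of LPS against unstimulated cells. The spread of each peak, however, came from all 8 libraries in both comparisons, which can raise the overlap of their calls. Fenoterol + LPS against fenoterol gave 6296 peaks that rose and 2882 that fell, 13.7% of those tested. Of the 4363 peaks that rose with LPS alone, 3204 (73.4%) also rose here, where independent lists of these sizes would share 411, and 0 fell. Of the 2362 that fell with LPS alone, 934 (39.5%) also fell here, where independent lists would share 102, and 3 rose. Counted by direction in each mouse, 4165 of the 4363 risen peaks (95.46%) were higher with fenoterol + LPS than with fenoterol in both mice, against 32.6% of all tested peaks. Of the fallen peaks, 2043 (86.49%) were lower in both mice, against 37.1% of all. Median accessibility of the risen peaks was 12.2 RPKM with fenoterol and 29.5 RPKM with fenoterol + LPS, beside the 10.8 and 28.4 RPKM without fenoterol. That of the fallen peaks was 32.9 RPKM with fenoterol and 22.3 RPKM with both, beside 37.2 and 21.5 RPKM. The median log2 change was 0.999 against 1.09 for the risen and -0.458 against -0.70 for the fallen peaks, the values without fenoterol being those the peaks were chosen on. The shares called again in the 2 directions were not tested against each other, and the fallen peaks had the smaller changes.

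All 12 named risen peaks were higher with fenoterol + LPS than with fenoterol. The chromosome 14 region at 103457007 went from 8.18 ± 7.37 RPKM with fenoterol to 79.5 ± 29.5 RPKM with both (SD, n = 2), and the chromosome 12 region at 56588293 from 8.66 ± 0.202 to 64.2 ± 4.14 RPKM. Of the 12 named fallen peaks, 11 were lower with fenoterol + LPS than with fenoterol. The exception was at 22203555 to 22203754 on chromosome 9, with 17.3 ± 7.37 RPKM unstimulated, 9.89 ± 0.613 with fenoterol, 3.52 ± 3.06 with LPS, where mouse 2 was at the floor of 1 read, and 14.6 ± 0.868 with both; its LPS call was lost without the unstimulated library of mouse 1 (adjusted p = 0.12) and without the LPS library of mouse 2 (0.139). At least 2-fold changes in both mice numbered 2485 up and 191 down, with 7 in opposite ways. The total of 9178 peaks became 3731 without the fenoterol library of mouse 1, 4189 without the fenoterol + LPS library of mouse 1 and 4073 without that of mouse 2.

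Similarity of the LPS response was also measured across animals, setting LPS minus unstimulated in 1 mouse against fenoterol + LPS minus fenoterol in the other. Across the 66786 peaks, which are not independent replicates, Pearson's r was 0.476 and 0.581 for the 2 directions and Spearman's rho 0.407 and 0.485. The LPS response without fenoterol had r = 0.478 between the mice and that with fenoterol r = 0.664. The response to LPS thus correlated across fenoterol states as closely as it did between mice within the state without fenoterol.

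Few regions passed the threshold with fenoterol alone for 15 min. Recovery of changes was not simulated for this comparison, so changes may have been missed. Against unstimulated cells, 4 peaks rose and 1 fell, with 4968 peaks at an unadjusted p under 0.05 where 3339 are expected by chance. The peak at 106147045 to 106147777 on chromosome 5 rose from 32.3 ± 5.35 to 75.8 ± 7.41 RPKM (SD, n = 2; 2.20-fold, adjusted p = 0.00587). It stood at 33.3 ± 3.16 RPKM with LPS and at 33.2 ± 2.81 RPKM with fenoterol + LPS. The peak at 56893474 to 56893894 on chromosome 18 rose from 17.7 ± 4.92 to 53.3 ± 7.04 RPKM (2.67-fold, adjusted p = 0.00153) and was at 39.9 ± 1.11 RPKM with LPS and 41.9 ± 2.89 RPKM with both. On chromosome 2, the region at 167519845 to 167520084 rose from 5.13 ± 1.57 to 32.4 ± 15.4 RPKM (adjusted p = 0.0252), with 15.1 ± 0.462 RPKM under LPS. The region at 17513779 to 17514389 on chromosome 12 rose from 23.2 ± 0.00411 to 46.2 ± 1.60 RPKM (adjusted p = 0.0256), close to its 43.5 ± 1.23 RPKM with LPS. The peak that fell, at 63764295 to 63764497 on chromosome 14, went from 43.0 ± 7.05 to 11.5 ± 5.30 RPKM (adjusted p = 0.0256). Of 21 alternatives, the call on chromosome 12 was lost in 8, that on chromosome 14 in 7, that on chromosome 2 in 6, that on chromosome 5 in 3 and that on chromosome 18 in 2. For the chromosome 14 peak these included voom (adjusted p = 0.061), the pseudocount 5 times lower (0.0601) and leaving out the unstimulated library of mouse 1 (0.158).

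The smallest adjusted p short of the threshold was at 6595147 to 6595783 on chromosome 11, with 24.2 ± 0.595 RPKM unstimulated and 44.7 ± 1.86 RPKM with fenoterol (adjusted p = 0.0666). Changes of at least 2-fold in both mice numbered 29 up and 18 down, against 35 that went in opposite ways. The count of 5 rested on single libraries. It was 3550, with 1728 risen and 1822 fallen, without the unstimulated library of mouse 2, which leaves the shallow one of mouse 1 alone in its group, 0 without the fenoterol library of mouse 1, 8 without the unstimulated library of mouse 1, and 2 or 3 without any 1 of the other 5. With the mouse as a block it was 8, with 7 risen and 1 fallen. By voom on recovered reads it was 46, with 43 risen and 3 fallen, the latter not including the chromosome 14 peak. By voom without the unstimulated library of mouse 2, 8 rose and 76 fell, and without the fenoterol library of mouse 1, 17 rose and 0 fell. The limma-trend count was 10 on the values as deposited, with 9 risen and 1 fallen, and 30 after quantile normalization, with 29 risen and 1 fallen.

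**Figure D2:**
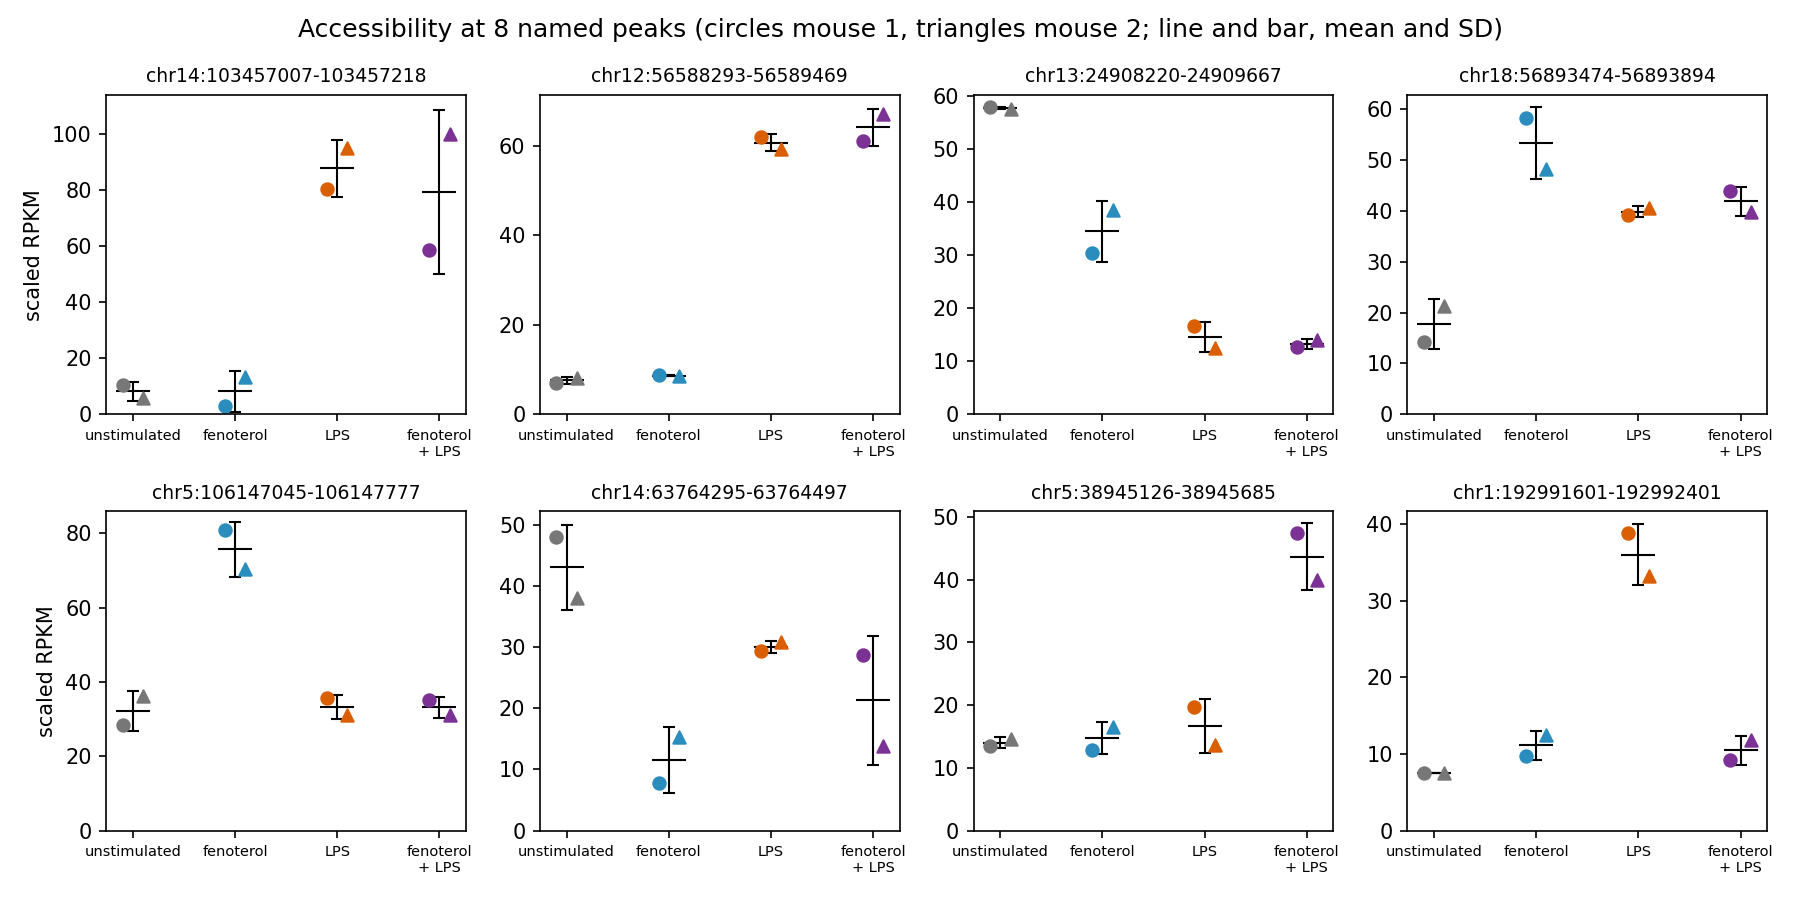
Scaled RPKM of 8 named peaks in the 4 groups, each y axis starting at 0; circles are mouse 1, triangles mouse 2, and the line and bar give the mean and SD (n = 2). The chromosome 5 peak at 106147045 stood at 75.8 RPKM with fenoterol and at about 33 RPKM in each other group, while the chromosome 1 peak at 192991601 reached 36.0 RPKM with LPS and 10.5 RPKM with fenoterol + LPS.

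The series title concerns β2 adrenergic signalling and early Il1b transcription in macrophages. Its effect on the chromatin of LPS-stimulated cells was measured by comparing fenoterol + LPS with LPS; peaks at Il1b are not analysed here. No peak passed the threshold by limma-trend: 0 rose and 0 fell, with a smallest adjusted p of 0.162 and 4445 peaks at an unadjusted p under 0.05 where 3339 are expected. Voom on the recovered reads, a test added after the data were seen, called 389 peaks higher and 34 lower. Limma-trend on the 4 libraries with LPS alone, also added then, called 228 higher and 28 lower, so the outcome rested on the test and on the libraries that set the spread. Changes of at least 2-fold in both mice numbered 60 up and 10 down, with 4 in opposite ways. The differences of the 2 mice correlated with r = 0.238 across peaks, where those of fenoterol against unstimulated cells correlated with r = 0.0418. With all libraries thinned to equal depth these were 0.0964 and 0.0221.

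Of the 10 named peaks, the 5 with the smallest unadjusted p in each direction, 8 passed by voom. The peak at 192991601 to 192992401 on chromosome 1 had 7.49 ± 0.0322 RPKM unstimulated, 11.2 ± 1.92 with fenoterol, 36.0 ± 4.04 with LPS and 10.5 ± 1.90 with both (SD, n = 2); its log2 difference was -1.47 (SE 0.26, adjusted p = 0.162; 2.25e-10 by voom). The peak at 38945126 to 38945685 on chromosome 5 had 14.0 ± 0.893, 14.7 ± 2.57, 16.7 ± 4.36 and 43.7 ± 5.35 RPKM in the same order, a 2.33-fold difference (adjusted p = 0.162; 1.79e-06 by voom). A peak on chromosome 2 at 148356135 to 148356691 had 37.9 ± 3.98 RPKM with LPS and 70.8 ± 7.89 with both (adjusted p = 0.162; 1.48e-05 by voom). The peak at 75534462 to 75534847 on chromosome 2 had 34.1 ± 0.478 RPKM with LPS and 15.2 ± 1.05 with both (adjusted p = 0.162; 0.00665 by voom). By limma-trend the count was 23 without the unstimulated library of mouse 1, 20 without that of mouse 2 and 0 without any 1 of the other 6. By voom it was 20 without the LPS library of mouse 1, 21 without that of mouse 2 and 41 without the fenoterol + LPS library of mouse 1.

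At regions where LPS acts, fenoterol shifted accessibility little. Peaks were selected for an at least 2-fold LPS response in 1 mouse and measured in the other. The 4584 peaks gained in mouse 1 and the 3024 gained in mouse 2 had a median log2 difference between fenoterol + LPS and LPS of 0.08 in the other mouse in both cases (0.0813 and 0.0787). Random peak sets matched on mean value had medians of 0.031 and 0.045, and the observed values lay at the 100th and 99.99th percentiles of 10000 sets. The 1448 peaks lost in mouse 1 and the 905 lost in mouse 2 had medians of -0.031 and -0.0584, at percentiles of 0.01 and 0. These percentiles cover the spread over peaks, which are not independent replicates, and not that between animals. Matching used the mean over all 8 libraries, so matched peaks need not have the same level with LPS. Measured in the other mouse, LPS itself moved the gained peaks by medians of 0.647 and 1.03. Fenoterol without LPS moved the 4584 peaks gained in mouse 1 by a median of 0.0661 in mouse 2. It moved the 3024 gained in mouse 2 by -0.16 in mouse 1. These medians have opposite signs but are of differently selected sets, and the second rests on the shallow unstimulated library of mouse 1. The shift at gained peaks averaged 0.00875 with a pseudocount 5 times higher, against 0.08. That at lost peaks averaged -0.113 with this pseudocount, against -0.0447.

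**Figure D3:**
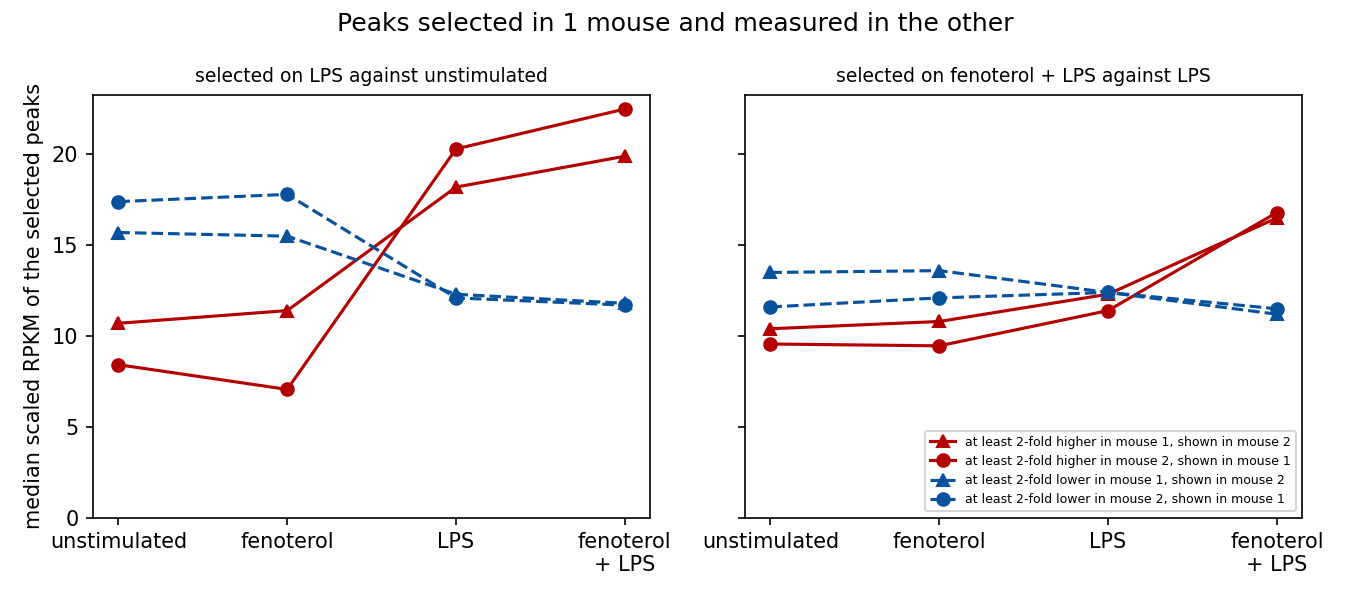
Median scaled RPKM of peaks selected in 1 mouse and shown in the other, over the 4 groups; solid lines are peaks at least 2-fold higher and dashed lines at least 2-fold lower, selected on LPS against unstimulated (left) or fenoterol + LPS against LPS (right). LPS-gained peaks stood at 18.2 and 20.3 RPKM with LPS and at 19.9 and 22.5 RPKM with fenoterol + LPS.

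Dependence of the fenoterol effect on LPS was tested as an interaction. No peak passed by limma-trend, with a smallest adjusted p of 0.262 and 4224 peaks at an unadjusted p under 0.05 where 3339 are expected. The positive interaction with the smallest unadjusted p was at 28373038 to 28373244 on chromosome 8, where the mean was 24.9 ± 0.612 RPKM unstimulated, 11.2 ± 3.52 with fenoterol, 35.1 ± 8.68 with LPS and 60.1 ± 12.2 with both (SD, n = 2; adjusted p = 0.262). Voom called 4 peaks, 1 with a positive and 3 with a negative interaction. These 4 were named after their values were seen. They were the chromosome 1 peak at 192991601 (adjusted p = 8.07e-05), the fenoterol-raised chromosome 5 peak at 106147045 (adjusted p = 0.00283), a peak at 40925906 to 40927074 on chromosome 12 (adjusted p = 0.00267) and a peak at 150245722 to 150246327 on chromosome 4 (adjusted p = 0.0424), all by voom. The voom count was 1 without the LPS library of mouse 1, 2 without the fenoterol library of mouse 2, 2 without the fenoterol + LPS library of mouse 1, 17 (11 positive, 6 negative) without the unstimulated library of mouse 1 and 13 (12 positive, 1 negative) without that of mouse 2. By limma-trend the count was 278 without the unstimulated library of mouse 2, 0 without any 1 of the other 7, and 1 with the mouse as a block, namely the chromosome 8 peak at 28373038 (adjusted p = 0.0347). Across mice, the fenoterol response without LPS in 1 animal and with LPS in the other correlated with r = 0.0141 and 0.0502 (rho 0.0186 and 0.0498), each way over the same 66786 peaks. Between the mice within a state, the fenoterol response correlated with r = 0.0418 without LPS and 0.238 with LPS. With so little agreement in the state without LPS, the low correlation across states cannot show that the responses differ.

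Averaged over both fenoterol states in an additive fit of 4 libraries against 4, LPS raised 8661 peaks and lowered 6612, together 22.9% of those tested. After quantile normalization 8630 rose and 8090 fell, a more even balance. Averaged over both LPS states, fenoterol changed 0 peaks by limma-trend, with a smallest adjusted p of 0.195 and 4875 peaks at an unadjusted p under 0.05. Voom gave 178 higher and 26 lower for fenoterol. By limma-trend the fenoterol count was 5 without the unstimulated library of mouse 2, 1 without that of mouse 1, 1 without the fenoterol + LPS library of mouse 1 and 0 without any 1 of the other 5.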

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

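The peaks in this part were picked by the planned naming rule for the interaction, and the direction of the fenoterol effect in each mouse was looked at only after the fit. At 8 of the 10 named peaks the fenoterol difference went 1 way in both mice without LPS and the opposite way in both mice with LPS. Over all 66786 tested peaks this held for 8863 (13.3%), where chance gives 12.5%, so the share is near chance and the 8 stand out through being picked. The interaction test of limma-trend passed none of them without a block. With the mouse as a block it passed the chromosome 8 peak at 28373038 (adjusted p = 0.0347), and without the unstimulated library of mouse 2 it passed all 8, with adjusted p from 0.0132 to 0.0459.

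At 5 of the peaks fenoterol went with lower accessibility without LPS and higher with it. The interaction, the log2 difference with LPS minus that without, was 1.66 at 28373038 to 28373244 on chromosome 8 (adjusted p = 0.262), 1.44 at 88428977 to 88429272 on chromosome 3 (0.269), 1.5 at 89153652 to 89153955 on chromosome 4 (0.269), 1.17 at 33564886 to 33565256 on chromosome 11 (0.269) and 1.05 at 34878564 to 34878884 on chromosome 5 (0.309). At 3 it went the other way, with an interaction of -1.49 at 107861186 to 107861434 on chromosome 1 (0.332), -1.86 at 192991601 to 192992401 on chromosome 1 (0.372) and -1.14 at 43860555 to 43861121 on chromosome 13 (0.433). Of these 8, the chromosome 1 peak at 192991601 passed by voom (adjusted p = 8.07e-05). There the fenoterol difference was 0.27 and 0.52 in the 2 mice without LPS and -1.71 and -1.23 with LPS.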

How the results depend on the processing

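Voom, cyclic loess and the fits on 4 libraries were chosen after seeing the data; the other settings were planned. With all 8 libraries, call counts for LPS kept within 1.5 times under all settings but those named below, while every count for fenoterol moved with the test. Leaving out 1 library in turn gave 2077 to 12508 peaks for LPS against unstimulated, 0 to 3550 for fenoterol against unstimulated, 0 to 23 for fenoterol + LPS against LPS, 3731 to 12606 for fenoterol + LPS against fenoterol, 0 to 278 for the interaction, 11629 to 15838 for the average LPS effect and 0 to 5 for the average fenoterol effect. A library left alone in its group was assumed to vary like the other groups. Fewer samples enter those fits; the cause of the other differences was not tested. The balance of risen and fallen peaks did change without the unstimulated library of mouse 2: fenoterol against unstimulated went from 4 risen and 1 fallen to 1728 and 1822 by limma-trend and from 43 and 3 to 8 and 76 by voom, and the interaction by voom from 1 positive and 3 negative to 12 and 1. Leaving out 1 library by voom gave 2257 to 8183 for LPS against unstimulated, 17 to 84 for fenoterol against unstimulated, 20 to 614 for fenoterol + LPS against LPS, 8275 to 14162 for fenoterol + LPS against fenoterol and 1 to 17 for the interaction. Of 1221 values for named peaks, 0 changed sign, 1074 stayed on their side of the threshold, 39 dropped out and 108 came in.

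With the mouse as a replicate block, fenoterol against unstimulated gave 8 peaks (5 without it) and the interaction 1 (0 without it); no other call count of limma-trend moved by over 1.5 times. Without a mean trend, LPS against unstimulated gave 3911 peaks (6725 with it) and fenoterol against unstimulated 0.

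Fenoterol against unstimulated gave 10 peaks on the values as deposited, 30 after quantile normalization, 26 after cyclic loess, 46 by voom, 51 by voom with the block and 75 by voom with cyclic loess. Fenoterol + LPS against LPS gave 2 after quantile normalization, 3 with a pseudocount 5 times higher, 256 on its 4 libraries alone, 423 by voom, 526 by voom with the block and 501 by voom with cyclic loess. The interaction gave 4, 9 and 15 by voom, voom with the block and voom with cyclic loess. The average fenoterol effect gave 1 on the values as deposited, 4 after quantile normalization, 1 after cyclic loess, and 204, 298 and 247 by the same 3 forms of voom. Fenoterol + LPS against fenoterol gave 13955 by voom with the block (9178 by limma-trend).

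Counts of peaks changed at least 2-fold in both mice follow from the pseudocount, the filter and the threshold. For LPS against unstimulated (1699) they were 2849 and 113 with the lower and the higher pseudocount and 5948 at 1.5-fold. For fenoterol against unstimulated (47) they were 257 and 0 with these pseudocounts, 25 after quantile normalization, 74 with no filter, 21 with the lowest 25% of peaks left out and 897 at 1.5-fold. For fenoterol + LPS against LPS (70) they were, in the same order, 274, 0, 116, 208, 35 and 1248. For fenoterol + LPS against fenoterol (2676) they were 4130 and 250 with these pseudocounts and 8238 at 1.5-fold.

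The mean log2 shift by fenoterol at LPS-gained peaks (0.08) was 0.0834 as deposited, 0.0585 after quantile normalization, 0.102 and 0.00875 with the lower and the higher pseudocount, 0.106 with no filter, 0.0763 with the lowest 25% left out and 0.0767 at 1.5-fold. At LPS-lost peaks (-0.0447) it was -0.0417 as deposited, -0.0296 after quantile normalization, and -0.0207 and -0.113 with these pseudocounts. There it was also -0.0208 with no filter, -0.0557 with the lowest 25% left out and -0.0249 at 1.5-fold. The cross-mouse correlations, 0.529 for LPS and 0.0321 for fenoterol on average, moved by less than their spread over the 2 directions under all 6 settings tried. Depth limits the unstimulated library of mouse 1 most, with 1426873 reads. Gene-list, Il1b, promoter, motif and 1 peak per gene results were not run because no annotation or sequence of build mm9 was used here.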

Other observations

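The tests on pooled spread, on peak height trends, on peaks lower with fenoterol + LPS, on the tallest peaks, on splits for the average fenoterol effect by limma-trend and on splits balanced over the mice were chosen only after their results were seen, as were voom and the regions named in this part. The 389 peaks that voom called higher with fenoterol + LPS than with LPS were weakly open in the other states. Their median was 12.1 RPKM unstimulated, 12.5 with fenoterol, 15.9 with LPS and 32.3 with both, the last 2 being the groups they were chosen on. In 132 of them (33.9%) fenoterol without LPS was also above unstimulated in both mice, against 23.8% of all tested peaks, but the median difference was -0.02 in mouse 1 and 0.08 in mouse 2. Among them 58 had risen with LPS alone, where independent lists share 25.4, although the shared LPS libraries lower this overlap. The 34 peaks called lower had medians of 27.9 RPKM unstimulated, 26.6 with fenoterol, 35.8 with LPS and 21.1 with both. Of these, 12 had risen with LPS, where independent lists share 2.22; the shared LPS libraries raise this overlap. Measured across animals, the 739 peaks at least 2-fold higher with fenoterol + LPS than with LPS in mouse 1 had a median LPS response of 0.19 in mouse 2, above all 10000 matched random sets. The 536 so chosen in mouse 2 had 0.28 in mouse 1, at the 99.76th percentile. Their fenoterol response without LPS lay at the 90.19th and 3.94th percentiles. All these percentiles cover the spread over peaks, not that between animals.

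Peaks that rose with LPS lay near each other. Of the 4363, 33.2% had another risen peak 2 to 20 kb away. In 1000 draws the share was 19.2% to 24.4%. The draws kept the chromosome and, in 5 coarse classes each, mean value and the number of tested peaks nearby. A gathering of risen peaks beyond local peak density is a hypothesis only, since density and mean value were not held within a class. For the 2362 fallen peaks the share was 25.9% against 12.7% to 18.2%. Linking risen peaks at most 20 kb apart gave 44 runs of at least 5 peaks, holding 265 peaks. A run on chromosome 14 from 103411638 to 103458676 held 10 risen peaks among 15 tested, with log2 changes from 0.56 to 2.94. Runs of 10 also lay on chromosome 4 at 102242771 to 102298056, with 11 tested, and at 144842507 to 144890678, with 14 tested. On chromosome 2, 8 of 10 tested peaks from 164247502 to 164282671 rose and 1 fell. The median log2 change of these risen peaks was 1.5 with LPS alone and 1.89 for fenoterol + LPS against fenoterol. Between fenoterol + LPS and LPS their median difference was only 0.0507. In the same order, the medians with LPS alone and against fenoterol were 1.17 and 1.28 in the chromosome 14 run. They were 0.932 and 0.615 in the chromosome 4 run at 102242771, and 0.843 and 1.09 in that at 144842507.

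The first pattern weighed is the 0 peaks by limma-trend against 423 by voom between fenoterol + LPS and LPS. Chance differences between libraries are argued against for the higher peaks. Of those at least 2-fold higher in 1 mouse, a mean of 77.4% were higher in the other (76.2% and 78.5%). Over all peaks, which were not matched on mean value, the shares were 50.2% and 49.7%. Their medians in the other mouse were 0.324 and 0.41, where the highest of 10000 matched random sets had 0.112 and 0.159. Such sets cover the spread over peaks, not that between animals. For peaks at least 2-fold lower the agreement was smaller: their medians in the other mouse were -0.098 and -0.0828 (mean -0.0904), with 39.2% and 42.4% higher, though both medians lay below all 10000 matched random sets. A trend of signal with peak height is argued against, since voom after cyclic loess called 501, and spread pooled from the other groups is a candidate explanation for the 0, as limma-trend on the 4 libraries with LPS alone called 256 and the median SD was 0.201 in the unstimulated group and 0.127 in both groups with LPS. An effect of the agonist, of the time since it was given, or of handling shared by the 2 libraries of a group stays open and was not tested, and voom called 20 without the LPS library of mouse 1, 21 without that of mouse 2 and 41 without the fenoterol + LPS library of mouse 1.

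The second pattern is the unstimulated library of mouse 1, which correlated at 0.853 to 0.863 with the other 3 libraries without LPS while those correlated at 0.901 to 0.911 with each other. Thinned to its number of reads, those 3 correlated at 0.782 to 0.786 with each other and at up to 0.803 with it. Shallow depth may thus account for its low correlations. The comparison is not even, because its empty peaks stayed set to 1 read while peaks emptied by thinning did not. Thinning left its highest RPKM of 332 above the 190 to 233 of the others. Across the 8 libraries the highest RPKM fell with depth (Pearson r = -0.985, exact permutation p = 0.00062; Spearman rho = -0.929, exact permutation p = 0.00223; 1 relation computed, two-sided). The 2 unstimulated libraries are farthest from the median depth. Without them r was -0.81 (exact permutation p = 0.0444) and rho -0.829 (exact permutation p = 0.0583). This relation was chosen after the 332 RPKM was seen, so these p-values are not independent support for it. Before thinning, the highest RPKM of the others was 190 to 221, so fewer reads alone did not bring their tallest peaks near 332. The cause of the relation stays open, and no biological explanation was tested.

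The third pattern is that fenoterol differences agreed between mice more with LPS than without. The between-mouse covariance was 0.0299 (jackknife SE over chromosomes 0.00113) with LPS and 0.00636 (SE 0.000667) without. The difference of covariances was 0.0235 (SE 0.00188) with all libraries thinned to equal depth and 0.0236 before. Thinning adds noise to each library separately, which leaves a covariance between mice nearly unchanged. It therefore does not decide whether unequal depth plays a part. A peak height trend is argued against, with 0.0239 (SE 0.00114) after cyclic loess. The SEs cover the spread over chromosomes, not that between animals. Time since the agonist, 15 min against 15 min and a further 1 h, and preparation shared within a group stay open, because the design ties both to the presence of LPS.

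Other splits of the 8 libraries bear on the average effects. For LPS, 1 of the 34 splits that could be fitted, the real one, gave as many as the 15273 peaks, and the highest of the others gave 0. This would exclude chance only if libraries could be exchanged freely between the mice. The samples are paired by mouse, so that condition is not met. The 17 of these splits with 2 libraries of each mouse on each side, as in the real one, are too few for a share under 5%; there too 1, the real one, gave as many, and the highest other gave 0. The other splits hold the LPS effect in their residual spread, which works against calls in them: its median SD was 0.216 in the real split and 0.255 to 0.278 in the others. For fenoterol by limma-trend the real count was 0, which all 34 splits reach by construction, so the splits test nothing there. For fenoterol by voom, 2 of the 34 splits gave at least the real 204 and the highest other gave 582, so chance cannot be excluded. Of the 17 balanced over the mice, too few for a share under 5%, 1, the real one, gave as many, and the highest other gave 88. The split with 582 parts the libraries with LPS as the real one does and parts those without LPS by mouse.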
